A study of Arabidopsis thaliana with 6 samples.

How the data were processed

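Transcript levels were measured on 1-colour Affymetrix arrays in cotyledons of Arabidopsis thaliana, with 3 arrays of wildtype (Col-0) and 3 of the apl mutant. Per the labels' protocols, cotyledons of 6-day-old seedlings were cultured in an induction medium with 2,4-D at 1.25 mg/L, kinetin at 0.25 mg/L and bikinin at 10 µM, and were collected 72 h later. Total RNA was labelled with biotin and hybridised, 1 sample to an array. The deposited values are log2 signals of 38408 probe sets. RMA, which corrects background, equalises arrays and summarises probes, is named without a version in the submitters' processing notes, and how arrays were grouped in that step is not given in the sources used here. RMA values have no detection call, so a low signal cannot be told from background, and summarising pulls in the differences of dim transcripts. The number of arrays limits the precision. The median log2 signal per array lay between 6.05 and 6.25, and Pearson's r over probe sets was 0.969 to 0.977 within groups and 0.949 to 0.974 between them.

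Probe sets were named only through the platform annotation supplied with the values. Of the 38408 probe sets, 16722 were paired with 1 gene, 759 with several and 20927 with none, and the last are unnamed here. Of the singly named probe sets, 16574 matched a locus in the RefSeq table of assembly TAIR10.1, which was used only for names and for which genes neighbour each other. They stand for 16548 distinct genes, of which 1762 have a name other than the locus code. Where a gene had more than 1 probe set, the brightest was used. No probe set is paired with APL in that annotation, so the level of APL, which would check the labels, is not analysed here.

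The deposited log2 values were fitted without further scaling with lmFit and eBayes of limma 3.58.1 in R 4.3.3, apl against wildtype, with all 38408 probe sets tested 2-sided. Calls are Benjamini-Hochberg adjusted p-values under 0.05. Gene lists were tested against all other probe sets with camera at a preset correlation of 0.01, for the 6 lists with at least 3 measured members, and again with an estimated correlation and with fry. Figures were drawn with matplotlib 3.10.9. On simulated data for apl against wildtype, with 200 of 38408 probe sets changed, the fit recovered 0% of changes of 1 log2 unit, 48.5% of changes of 2 and 92% of changes of 4. Camera recovered a list of 8 bright genes that were all shifted by 1 log2 unit. The simulated noise was independent between probe sets, whereas the xylem wall and cell death list had an estimated correlation of 0.87. The simulation therefore says little about camera on correlated lists.

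The groups, tests, 18 gene lists with 297 genes, thresholds and most alternatives were fixed before the data were examined. The genes named are the 12 largest rises and 12 largest falls among called, singly named genes whose groups do not overlap, and up to 4 members with the smallest p of each list. The lists cover late sieve elements, early phloem, companion cells and phloem transport, xylem wall and cell death, xylem regulators, cambium and procambium, cell cycle, photosynthesis, epidermis and guard cells, bundle sheath, auxin, cytokinin, brassinosteroid biosynthesis, defence, jasmonate and wounding, lignin, senescence, and reference genes. Of the 297 genes, 42 were measured under a name.

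Both groups share replicate numbers in the labels, and the data were checked for pairing by these numbers. Deviations from the group means correlated at 0.40 to 0.45 between arrays with the same number, in all 3 pairs, and at -0.29 to -0.16 between arrays of different group and number. Arrays with the same number also held 740 to 940 identical values, against 0 to 2 in the other 12 pairs of arrays. By the rule set for these correlations the number was taken to pair the samples, from the data and not from a statement in the labels. RMA run on each pair of arrays apart would also give shared values and deviations, so the pairing can lie in the processing and not in the cultures. A fit with the replicate block was an alternative from the start, and its values are given where they change the call of a gene or list named in the text or move a count by over 1.5 times. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

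Other alternatives were quantile normalization, median centring, filters on dim probe sets, a variance trend with robust prior, array weights, ordinary t-statistics, other thresholds, 1 probe set per named gene, the mean of a gene's probe sets, and leaving out each array. Removing the 7083 unnamed probe sets numbered below the first named one, and removing the named genes of a chromosome 1 run, were added after the data were seen.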

Results

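Gene expression was compared between wildtype and apl cotyledons after 72 h in VISUAL, a culture system in which leaf cells are induced to form vascular cells. APL is a MYB-type regulator of phloem identity, and the comparison asks which transcripts depend on it in this culture. There were 3 arrays per group. The 1st principal component held 39.7% of the variance and placed the wildtype arrays between -74.6 and -35.0, apl replicate 2 at 9.17, apl replicate 1 at 55.1 and apl replicate 3 at 85.2.

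Most of the called differences were losses of signal in apl. AT2G31540, a GDSL-type lipase gene, fell by 7.72 on the log2 scale (SE 0.80, n = 3 per group), a 211-fold difference in signal (limma, Benjamini-Hochberg adjusted p = 0.0156), which was 417-fold without apl replicate 2 and 137-fold without apl replicate 3. AT3G17380, which encodes a TRAF-like protein, fell by 5.79 (SE 0.40), or 55.5-fold, and AT1G64370 fell by 5.50 (SE 0.33), or 45.4-fold. The other 9 of the 12 largest falls were AT1G47271, AT3G25855, AT5G45520, AT1G69325, AT5G52270, AT2G32880, AT5G41470, AT4G13992 and AT1G61710. Across the 12 falls the mean log2 signal was 8.93 to 11.6 in wildtype and 3.26 to 6.03 in apl, and the adjusted p ran from 0.00313 to 0.0454 (limma). Leaving out 1 array moved the fold of 9 of the 12 by over 1.5 times, and it was largest without apl replicate 2 in 10. Folds are of signal: for AT2G31540 and AT2G32880 the apl mean lay under the 25th percentile of every array, where signal cannot be told from background, so the fold in transcript is not known.

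Fewer of the called differences were rises in apl, and these were by smaller factors. AT3G29970, a B12D-type gene, rose by 5.41 on the log2 scale (SE 0.69, n = 3 per group), or 42.7-fold (limma, Benjamini-Hochberg adjusted p = 0.0291), and the difference was 78.2-fold without apl replicate 3. AT2G13547 rose by 4.49 (SE 0.30), or 22.4-fold. XTH20, of the xyloglucan endotransglucosylase/hydrolases that remodel the cell wall, rose by 3.74 (SE 0.41), or 13.4-fold. The peroxidase gene AT2G38380 rose 7.57-fold, and the lipid-transfer type genes AT4G22470 and AT4G12490 rose 5.47-fold and 5.15-fold. The remaining 6 of the 12 largest rises were AT2G17850, AT5G61890, AT2G43660, AT2G14247, AT1G21990 and AT3G46280, and across the 12 the fold was 2.83 to 42.7. For AT3G29970, XTH20 and AT2G17850 the wildtype mean lay under the 25th percentile of every array. With the replicate block, AT3G46280 had an adjusted p of 0.0522 (limma), and the other 11 rises and all 12 falls stayed under 0.05.

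**Figure D1:**
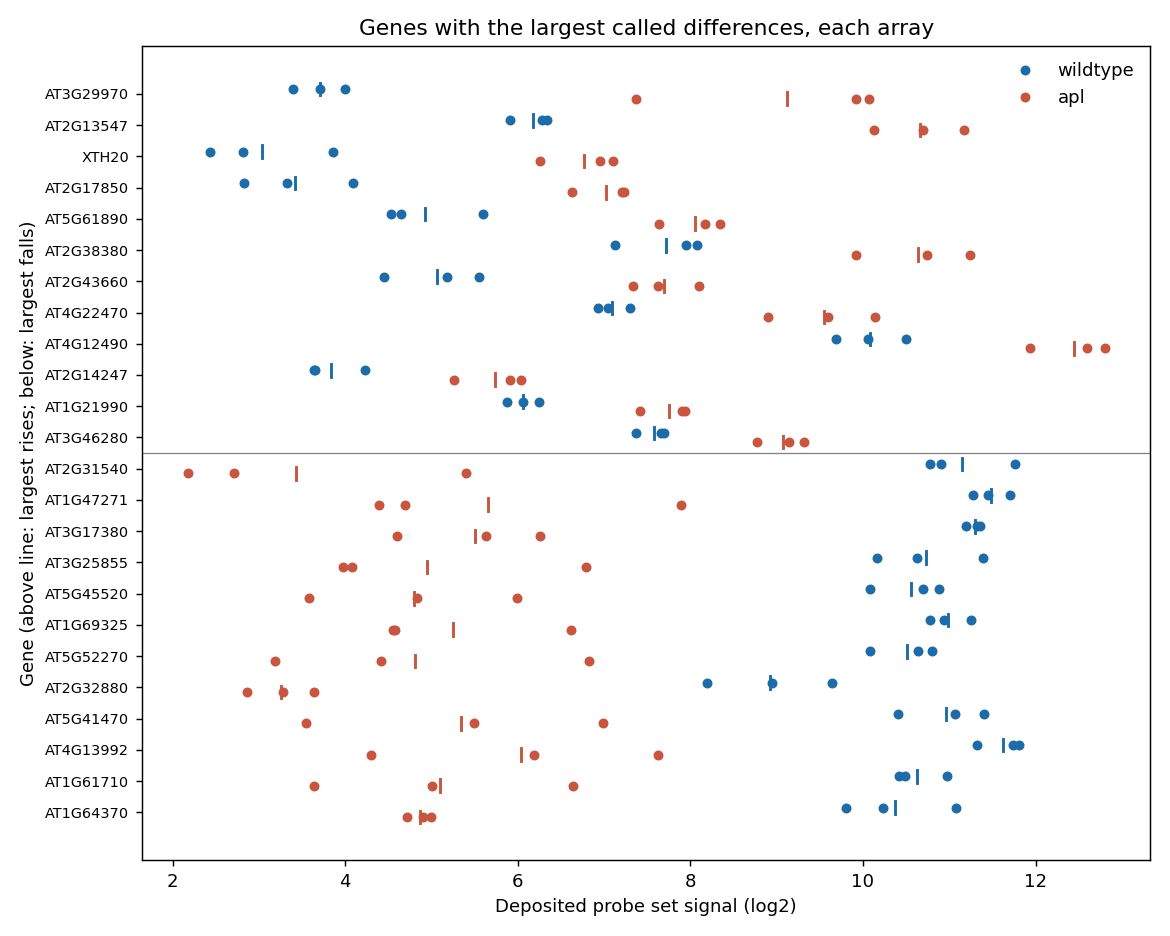
Deposited log2 signal (horizontal axis) of the 12 genes with the largest rises and the 12 with the largest falls (vertical axis), with a point per array, a bar at each group mean, wildtype in blue and apl in red. The 3 apl arrays lie on 1 side of the 3 wildtype arrays for each gene, and the group means of AT2G31540 differ by -7.72 log2 units, with an apl mean near background.

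In all, limma called 30 probe sets higher and 202 lower in apl among 38408 tested, each in the same direction in all 3 pairs of arrays. All 232 differed at least 2-fold, and 5 of the higher and 112 of the lower differed at least 8-fold. The shared direction and the 2-fold size follow largely from the call itself, since the simulation recovered 0% of changes of 1 log2 unit. They add no separate evidence. With the replicate block the counts were 81 and 340, of which 25 and 183 were shared with the fit without it. Of the 81, 21 are among the 7083 unnamed probe sets numbered below the first named one, whose nature is not given in the sources used here and which held 0 calls without the block. Among named genes, 19 were higher and 135 lower, and 30 and 225 with the replicate block, of which 16 and 121 were shared. Groups did not overlap for 15.2% of probe sets, where chance gives 10% for arrays that are not paired. The median log2 difference of all probe sets was 0.10, which quantile normalization brought to 0.05, and the calls under it were 29 higher and 244 lower. Counts of higher and lower calls were 1 and 20 without apl replicate 1, 22 and 308 without apl replicate 2, 19 and 132 without apl replicate 3, 2 and 22 without wildtype replicate 1, 2 and 22 without wildtype replicate 2, and 6 and 78 without wildtype replicate 3.

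Of the phloem lists, early phloem had 8 of 22 genes measured, and none was called over all genes tested. CLE44, which encodes a TDIF peptide made in phloem, was 0.70 log2 units higher in apl (SE 0.17, n = 3 per group), with an adjusted p of 0.193 over all genes (limma). It was the 1 member past the threshold adjusted over the list alone. CLE41, which encodes the same peptide, differed by 0.47 (SE 0.25). CLE45 differed by -1.32 (SE 0.58), or by -0.64 without apl replicate 3, and OPL2 by -0.75 (SE 0.35). The list's median was 0.27 and its mean -0.07, with 5 members above 0 and 3 below, and camera gave an adjusted p of 0.805. SWEET11, a sucrose exporter of the phloem, was the 1 measured gene of 18 for companion cells and phloem transport and differed by 2.25 (SE 0.77, limma adjusted p = 0.435), or by 1.47 without wildtype replicate 3 and 3.01 without wildtype replicate 1. The 13 late sieve element genes were not analysed here, because no probe set is paired with them.

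Of 30 xylem wall and cell death genes, 4 were measured, all 4 lay below 0 in apl, and the median was -1.31, or -0.82 without apl replicate 3. Camera gave the list an adjusted p of 4.96e-05 at the preset correlation, and that call is lost with an estimated correlation (adjusted p = 0.278) and with fry (adjusted p = 0.183). IRX15 and IRX15-L, which together are needed for xylan of normal length, differed by -2.06 (SE 0.62) and -1.48 (SE 0.48). IRX10, a xylan xylosyltransferase, differed by -1.14 (SE 0.42) and PRX66, a peroxidase, by -0.83 (SE 0.30). No member was called over all genes (limma), 4 had an unadjusted p under 0.05, and 4 were lower when adjusted over the list alone. The regulator C3H14 differed by -0.90 (SE 0.39) and the lignin gene HCT by -0.99 (SE 0.46), each the 1 measured member of its list and neither past the test.

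Auxin response genes lay above 0 in 8 of 8 measured members, with IAA20 only at 0.002 and a median of 0.39. After quantile normalization or median centring 7 of 8 lay above 0. Of named genes with signal above the array-wide median, outside the chromosome 1 run described below, 63.3% lay above 0. LBD29 differed by 1.10 (SE 0.37) and GH3.5, an auxin-conjugating enzyme, by 0.84 (SE 0.29). No member was called (limma), and these 2 had an unadjusted p under 0.05. The mean log2 signal of LBD29 was only 2.42 in wildtype and 3.52 in apl. Both lay under the 25th percentile of every array, where signal cannot be told from background. Camera gave the list an adjusted p of 0.0712, or 0.0322 with the replicate block. An estimated correlation gave an adjusted p of 0.278 and fry 0.183. The median was 0.21 without apl replicate 3 and 0.61 without apl replicate 2, and the list passed at the preset correlation without apl replicate 1 (camera adjusted p 0.0329), apl replicate 2 (0.0173) or wildtype replicate 3 (0.0339). It did not pass without wildtype replicate 1 (0.187), wildtype replicate 2 (0.277) or apl replicate 3 (0.541). Nor did it with probe sets under the 25th (camera adjusted p 0.308) or 50th percentile (0.242) left out. ARR16, a type-A response regulator induced by cytokinin, differed by -1.57 (SE 0.51), with an adjusted p of 0.406 (limma), and was called with the replicate block, at 0.0387. The other measured cytokinin gene, ARR15, differed by -0.19 (SE 0.27).

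Markers of other cell types and states gave no call. The stomatal regulators FAMA, SPCH and MUTE differed by -0.45 (SE 0.28), 0.04 (SE 0.25) and 0.05 (SE 0.19), and camera gave the list an adjusted p of 0.495, with a median of 0.04 and a mean of -0.12. The bundle sheath gene SCL23 differed by 0.38 (SE 0.40), and the photosynthesis genes RCA and LHCB4.1 by -0.18 (SE 0.25) and 0.15 (SE 0.19). In the cell cycle list AUR1, MCM7 and AUR2 differed by 0.34 (SE 0.18), 0.33 (SE 0.22) and -0.11 (SE 0.21), with a camera adjusted p of 0.495. The cambium genes LHW and MOL1 differed by 0.18 and 0.21, and the defence genes SAG101 and PDF1.2 by 0.44 and 0.31. For MUTE, SCL23 and PDF1.2 the means of both groups lay under the 25th percentile of every array, so their lack of a call says little. The 4 reference genes TIP41L, SAND, UBC21 and GAPC2 lay between -0.20 and 0.22, with a camera adjusted p of 0.495. No gene of the brassinosteroid, jasmonate and senescence lists was measured under a name. Over all 42 measured list genes limma made 0 calls, with 4 higher and 5 lower at an unadjusted p under 0.05 and 1 lower with the replicate block. Families found by words in gene names gave 0 of 16 tests past the threshold, with a smallest adjusted p of 0.201 (Benjamini-Hochberg), but only 1762 of 16548 genes have a name to search, so most called genes could not be members and the result says little.

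**Figure D2:**
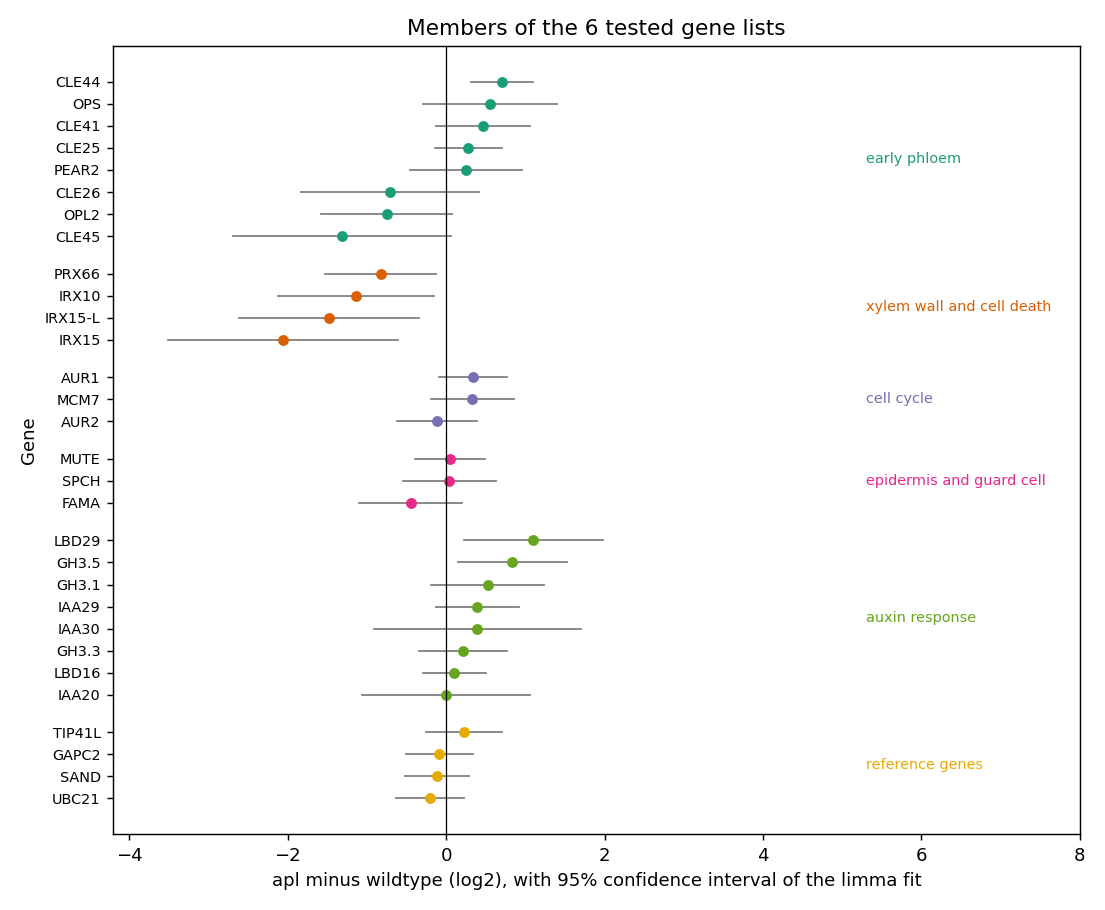
Difference of apl minus wildtype in log2 units (horizontal axis) for the measured members of the 6 tested lists (vertical axis), with lines for the 95% confidence interval of the limma fit. The 4 xylem wall genes lie below 0 with a median of -1.31, and the 8 auxin response genes lie above 0 with a median of 0.39.

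A run of neighbouring genes on chromosome 1, from AT1G07650 to AT1G09230, stood above the rest of the genome, and was looked for after the differences had been seen. Its 53 named genes with signal above the array-wide median had a median difference of 0.89 log2 units, with 25th and 75th percentiles of 0.67 and 1.09, and 50 of 53 lay above 0. The 27 dimmer named genes had a median of 0.21, and all 80 together 0.71. In the 3 pairs of arrays the medians of the 53 were 0.89, 0.85 and 0.97, those of the 27 were 0.42, 0.26 and 0, and those of all 80 were 0.73, 0.72 and 0.72. The 7705 such genes elsewhere had a median of 0.09. The run holds 5 of the 19 named genes called higher, AT1G07970, AT1G08220, AT1G08360, AT1G08580 and AT1G08845, each 2.26-fold to 2.40-fold higher, and 0 of the 135 called lower (limma). With the replicate block AT1G08580 had an adjusted p of 0.0542 (limma) and the other 4 stayed under 0.05.

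**Figure D3:**
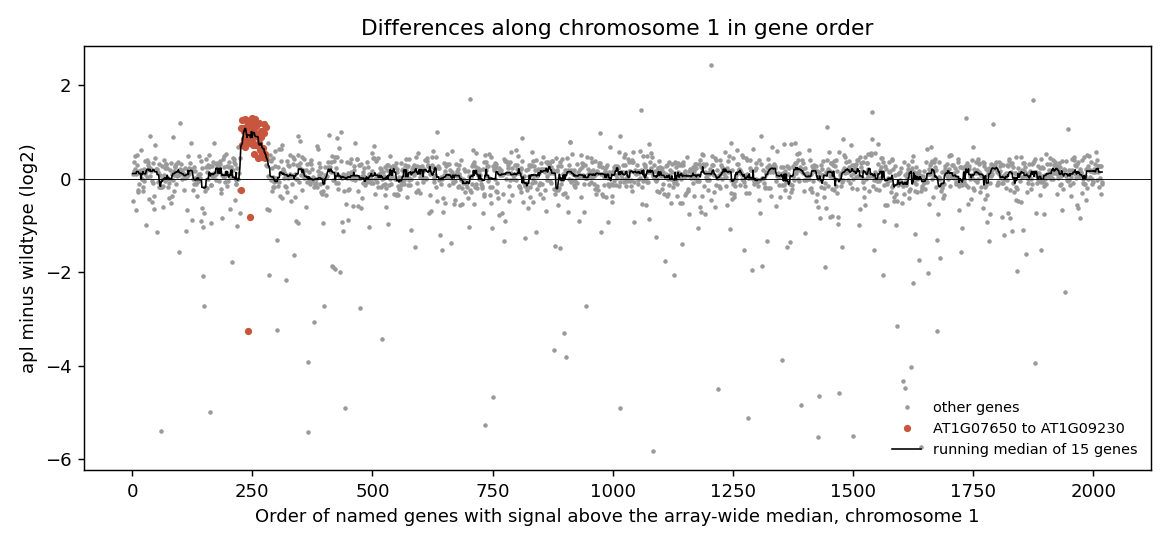
Difference of apl minus wildtype in log2 units (vertical axis) for named chromosome 1 genes with signal above the array-wide median, in gene order (horizontal axis), with a line for the running median over 15 genes. The red points from AT1G07650 to AT1G09230 have a median of 0.89, and the running median peaks there at 1.07.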

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

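All settings here were chosen before the data were examined, except leaving out the low-numbered unnamed probe sets or the named genes of the chromosome 1 run. Counts of probe sets higher in apl and probe sets lower in apl (limma) moved to 81 and 340 with the replicate block, 98 and 314 with a variance trend and robust prior, 2 and 35 at an adjusted p under 0.01, and 97 and 321 at 0.10. Higher calls moved to 61 and 112 with probe sets under the 25th and 50th percentiles left out, to 46 with 1 probe set per named gene, and to 61 without the 7083 low-numbered unnamed probe sets, each with fewer tests. Ordinary t-statistics made 0 and 0 calls, where 1791 higher and 1666 lower probe sets had an unadjusted p under 0.05 in limma. Leaving out 1 array gave 1 to 22 higher and 20 to 308 lower calls. Without apl replicate 2, 12 of the 30 higher and 167 of the 202 lower calls were shared. The cause of the other moves was not tested. The xylem wall list, with a median of -1.31, lost its call with an estimated correlation (adjusted p 0.278) and with fry (0.183), and its median ranged from -1.68 without apl replicate 2 to -0.82 without apl replicate 3, with camera adjusted p from 1.78e-06 to 0.00176. The early phloem list stayed uncalled throughout, at 0.13 to 0.40 without 1 array. The auxin list passed with the replicate block (camera adjusted p 0.0322) but not with an estimated correlation (0.278) or fry (0.183), and without 1 array its median ranged from 0.21 to 0.61 and its adjusted p from 0.0173 to 0.541.

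Values near 0 changed sign without a call. The median of the epidermis and guard cell list was -0.015 after median centring, -0.20 and -0.45 with the 25th and 50th percentile filters, and -0.19 to 0.14 without 1 array. SPCH was -0.015 and MUTE -0.010 after median centring. Without 1 array, SPCH ranged from -0.19 to 0.18, MUTE from -0.033 to 0.14, RCA from -0.41 to 0.016 and AUR2 from -0.21 to 0.047. Of the genes named by rule, the replicate block ended the call of AT3G46280 alone and brought a call of ARR16. It changed no other call of these genes or of a tested list except auxin. The variance trend with robust prior brought a call of CLE44 (limma adjusted p 0.0242). Of the 12 largest rises, quantile normalization ended 1 call and median centring 2, and array weights ended 1 of the 12 largest falls. Ordinary t-statistics ended the calls of all 12 and 12. Leaving out apl replicate 1 ended 11 of the 12 rises and 9 of the 12 falls, and leaving out apl replicate 3 ended 8 and 3. Leaving out wildtype replicate 1, 2 or 3 ended 10 rises each, and 9, 9 and 7 falls. Leaving out apl replicate 2 ended 3 rises and kept the calls of all 12 falls. Signals with no detection call limit what can be said of dim genes such as MUTE.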

Other observations

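The test over other splits of the arrays was planned; the family test by gene symbol and all tests of the 3 patterns below were chosen after the results were seen. Of the called genes with a name beyond a locus code, 10 fell in apl, and they are named after their values were seen. MYR2, a MYB-type factor of the same family as APL, fell by 4.21 on the log2 scale (SE 0.33), and the gene named PWD in the annotation (AT4G24450) fell by 5.09 (SE 0.47). The log2 difference was -3.23 for the tetraspanin TET6, -3.08 for GH9B17 and for UBC29, -2.79 for PM-ANT, -2.18 for GSTU18, -2.11 for the AP2-type factor LEP, -1.80 for SBT3.12 and -1.34 for SGP1. All had limma adjusted p-values under 0.05, also with the replicate block.

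Of 35 families sharing a symbol prefix, the ATG genes were the 1 past the threshold. The families were drawn from the 1762 of 16548 genes that have a name. Camera gave the ATG genes an adjusted p of 0.00416 at the preset correlation, a call that is lost with an estimated correlation (adjusted p 0.599). The set holds only ATG8B to ATG8H and ATG3, so it is nearly all 1 gene family and does not stand for autophagy genes at large. The median was -0.36 and 7 of 8 members lay below 0, also after quantile normalization and median centring. ATG8H differed by -2.21 (SE 0.40) and ATG8B by -1.07 (SE 0.29), and neither was called (limma adjusted p 0.0924 and 0.289).

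Of the 10 splits of the 6 arrays into 3 and 3, only the real one, 1 of 10, gave as many calls, with 232 against a highest of 0 in the others. With so few splits a share under 0.05 cannot be reached. With the replicate block, the real split gave 421 calls, against a highest of 0 among the other 3 splits that part all pairs.

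The chromosome 1 run reached a running median of 1.07 over 15 genes, against 0.39 in windows holding none of its genes, and among 10000 random gene orders the highest was 0.57, a permutation p of 0.0001, the smallest they can give. Sequence variation under the probes would lower the apl signal, whereas the run was picked for being higher in apl. Of 78 unnamed expressed probe sets numbered within the run, which had no part in finding it, 93.6% lay above 0. Since the direction of the run was known beforehand, that share adds little on this cause. A doubled copy of the segment in the apl line is a candidate explanation, since these 78 had a median of 0.903, near the 1 log2 unit of a doubling, while the 27 dim named genes lay at 0.21. Transcription that rises along the segment without added copies stays open and was not tested, as were any links to APL, which lies 8416 genes away on the same chromosome.

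In apl replicate 2 the fallen genes kept more signal, with the 269 probe sets called lower by at least 2 log2 units without it at a median of 16.6% of wildtype, against 5.44% in the other apl arrays. A compressed scale would shrink rises as well. The 53 bright genes of the chromosome 1 run had a median difference of 0.85 in pair 2, against 0.89 in pair 1 and 0.97 in pair 3. The median of pair 2 was the lowest, though close to that of pair 1. Pair 2 helped to pick these genes, and their differences are much smaller than the falls of at least 2 log2 units. These medians therefore cannot decide on a compressed scale, which stays open. The SD over all values was 2.73, against 2.69 to 2.78 in the other arrays, but RMA equalises arrays and so sets it. A constant share of wildtype RNA in that sample would hold every fallen gene at that share or above. Of 155 bright fallen probe sets, 7 (4.52%) lay more than 2 log2 units below the median. That is just under the limit of 5% used, so by this limit the share could explain the pattern, but the limit was chosen after the pattern had been seen. A further count, added after that result, goes the other way, since 11 of 155 lay below 5.52%, which is 50% of the share of 11.0% needed, and the lowest lay at 1.42%. The 10th percentile was 6.16%, and the median SD of these probe sets between wildtype arrays was 0.31 log2 units. For the probe sets this far below it, these values argue against a constant share of 11.0% as the only source. A smaller share was not tested. Whether wildtype RNA adds to the pattern stays open, and a real difference between cultures was not tested.

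Among 134 lower genes with a position, 5 pairs were neighbours, among them AT2G31540 with AT2G31550 and AT2G32870 with AT2G32880. Neighbours here are next to each other in the order of the 16348 named genes with a position, so genes without a named probe set can lie between them. Random placement gave a mean of 1.08 and a highest of 7 pairs in 10000 draws (permutation p 0.0054), which argues against chance positions. AT2G32870 is not called with the replicate block (limma adjusted p 0.0679), and genes called in both fits made 4 pairs (permutation p 0.0098), while the 222 called with the block made 13, against a mean of 3.0 (permutation p 0.0001, the smallest possible). Genes flanking the pairs had a median difference of 0.05. Shared control of neighbours and signal shared between similar copies both stay open and were not tested.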
